A study of Mus musculus with 12 samples.

How the data were processed

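Total RNA of 12 C57Bl/6 mouse liver samples was isolated with Trizol and measured with the nCounter mouse miRNA assay, per the labels' protocols and design text. The labels give the age of each liver and a mouse number from 1 to 3 within each age; e15.5 livers are of mixed sex and the postnatal livers are male, so sex and age cannot be told apart in comparisons with e15.5. The labels do not say whether an e15.5 sample of mixed sex is 1 embryo or a pool; if pools, the SDs at e15.5 are between pools and not between mice. The deposited table holds log2 values, and the only tool named in the submitters' processing notes is Partek 6.6. How background was subtracted and how samples were scaled is not given in the sources used here. A step per sample was taken as the median gap between neighbouring linear values under 40, using only gaps between 0.5 and 1.5. It lay between 0.78 and 1.28. Because only gaps in that range were used, the step does not show whether values are whole counts or how samples were scaled. The lowest value of every column was log2(0.001), or -9.97, which was read as at or below background. The table named 355 mouse probes, held no control probes and no identical columns, and 6 probes named 2 miRNAs each. Raw counts per lane were not used here, so counting intervals were not computed; the total linear signal per sample, between 148505 and 618776, is given in place of depth.

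Values were analysed as deposited. limma 3.58.1 (R 4.3.3) fitted 1 mean per age to all 12 samples, with moderated variances that follow the mean (lmFit, contrasts, eBayes with trend), and two-sided p-values were adjusted by the Benjamini-Hochberg method over the 355 probes, with 0.05 as threshold, separately for each of 6 pairs of ages and for the F tests over 4 and over 3 ages. The single level of miR-122 was also compared by an exact two-sided permutation test; with 3 livers against 3 its smallest p is 0.1. Because 4 of 12 sample medians lay at the floor and the bright probes shifted together between ages, changes were also given after each sample was centred on the mean of its 100 brightest probes (by mean over all samples; 1 of these has a floor value). In the text "after centring" means that scale. Floor values were moved by centring too, so centred calls of probes with floor values carry the shift of the bright probes. No fold is given against a group at the floor. A group at the floor in all 3 livers has no spread, so adjusted p-values of such probes are not a measure of precision.

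Lists of miRNAs (19, of which 16 had at least 3 probes) were fixed before the data were examined, from cell type, family and cluster knowledge: adult hepatocyte, erythroid, leukocyte, let-7, miR-17~92 and paralogous clusters, Dlk1-Dio3, stellate and mesenchymal, biliary and epithelial, muscle, pancreas, neural, miR-15/16/195/497, miR-29, miR-30, miR-34/449, pluripotent cell clusters, miR-23/27/24, miR-181 and endothelial. They were tested with camera (preset correlation 0.01), adjusted over the lists of each comparison, with an estimated correlation as an alternative. The adult liver also expresses miRNAs of several other lists, such as the endothelial one. The rule for named probes was fixed then too: miR-122; per comparison the 10 most raised and the 10 most lowered (5 for 7 against 2 weeks) among calls with no overlap between groups and a brighter group mean in the upper 50% of that group's means; all members of lists of up to 6, otherwise the 4 called members with the largest change; and the 10 brightest probes of each age. Since that rule picked mostly probes at the floor in 1 group, the same rule was applied, after the data were seen, to probes above the floor in all 6 samples of a comparison, and the text names from both; let-7e, miR-24, miR-22, miR-192, miR-106b, miR-146a and other leukocyte miRNAs at some ages, and the probes of the closing section, were chosen after their values were seen.

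Alternatives were a filter on the upper 50% of probes, quantile normalisation, the centring above, variances without a trend, only the 2 ages compared, the mouse number as a block, and each sample left out in turn; added after seeing the data were log2(linear + 1), log2(linear + 10), centring on the median of the 114 probes measured in every sample, and only those 114 probes. The steps were tested on simulated data: in 10 runs of the 2-week against e15.5 comparison with 100 of 355 probes changed, a log2 change of 1 was called for 89.3% of probes with a mean of 64 or more and for 7.6% of dimmer ones, a change of 3 for 100% and 33.1%, and 0.59% of unchanged probes were called. The simulation had no shift of bright probes between ages, unlike the data, and used 1 setting of spread and background. Its rates may therefore not hold for the real comparison. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15). For the closing section, probe names were matched to miRNA genes by symbol synonyms in a RefSeq gene table of assembly GRCm38.p6 (300 of 355 probes matched 1 gene), used only for which genes lie within 10000 bases of each other, since no genome build is given in the sources used here.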

Results

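MicroRNAs (miRNAs) were measured in livers of C57Bl/6 mice at 4 ages, embryonic day 15.5 (e15.5, mixed sex) and 2, 3 and 7 weeks after birth (males), with 3 liver samples per age and 12 in all. The nanoString nCounter assay counts hybridised barcoded probes directly, without amplification, and the table held 355 mouse probes as log2 values. The title of the series names miR-122, the dominant hepatocyte miRNA, as a regulator of the postnatal rise in hepatocyte ploidy, so the ages span the liver before and during that change. The total linear signal was 161535 ± 11974 (SD, n = 3) at e15.5, 533888 ± 73665 at 2 weeks, 502518 ± 32236 at 3 weeks and 249795 ± 16161 at 7 weeks. Values at or below background were all listed at 1 floor value, which held 44 to 143 probes per sample at e15.5, 146 to 163 at 2 weeks, 187 to 196 at 3 weeks and 107 to 182 at 7 weeks. Of the 355 probes, 114 were above the floor in all 12 livers. Across these 114 probes, correlations between livers of 1 age lay between 0.96 and 0.99. Those between postnatal ages lay between 0.91 and 0.98, and those between e15.5 and a postnatal age between 0.58 and 0.70. Probes with floor values were left out of these correlations, and probes are not independent replicates.

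**Figure D1:**
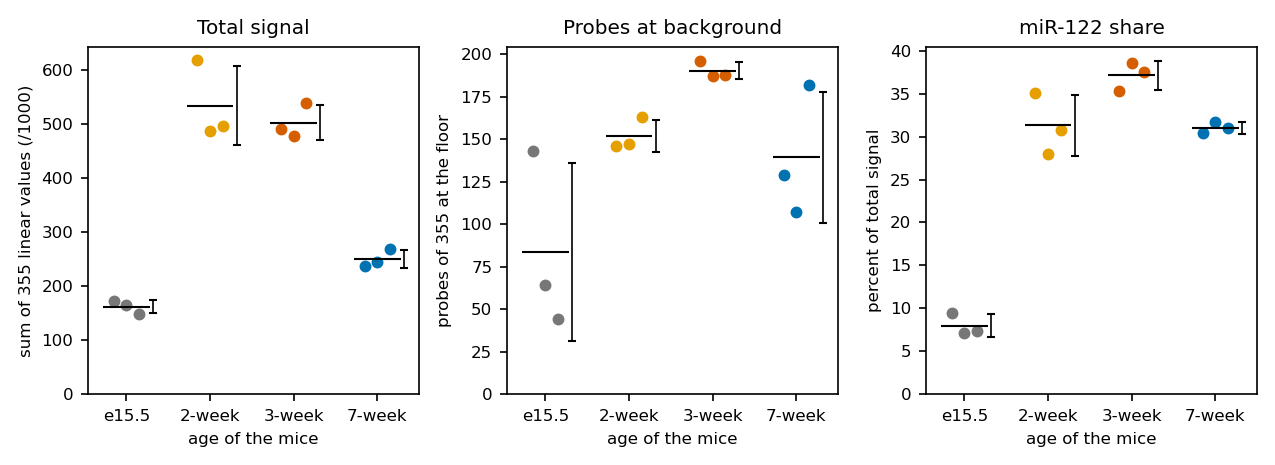
Total linear signal over 355 probes (divided by 1000), number of probes at the background floor and percent of the signal taken by miR-122, with 1 point per liver, lines at the means and bars for SDs (n = 3). The miR-122 share was 8.0% at e15.5 and 31.3%, 37.1% and 31.0% at 2, 3 and 7 weeks.

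The first question was how the level of miR-122 itself differed between the ages. Its log2 value was 13.64 ± 0.31 (SD, n = 3) at e15.5, 17.34 ± 0.35 at 2 weeks, 17.51 ± 0.12 at 3 weeks and 16.24 ± 0.10 at 7 weeks. Against e15.5 it was 13.0-fold higher at 2 weeks, 14.6-fold at 3 weeks and 6.07-fold at 7 weeks (limma, adjusted p = 5.1e-08, 3.0e-08 and 5.9e-07). In each of these comparisons every postnatal liver lay above every e15.5 liver, and the exact 2-sided permutation p was 0.1, the smallest that 3 livers against 3 can give. After each sample was centred on its 100 brightest probes, the same folds were 3.87, 5.59 and 5.04. As deposited, its value at 3 weeks did not differ from that at 2 weeks beyond the spread (log2 change 0.17, adjusted p = 0.79). After centring it was 0.53 higher at 3 weeks, which was not called (adjusted p = 0.076). From 3 to 7 weeks it fell by 1.27 on the log2 scale (adjusted p = 0.00029), whereas after centring the change was -0.15 (adjusted p = 0.56). From 2 to 7 weeks it fell by 1.10 (adjusted p = 0.00068), but after centring the change turned to 0.38 (adjusted p = 0.11). The share of the total signal taken by miR-122 was 7.98 ± 1.33% at e15.5, 31.3 ± 3.6% at 2 weeks, 37.1 ± 1.7% at 3 weeks and 31.0 ± 0.65% at 7 weeks.

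The comparison of 2-week with e15.5 livers describes the step from fetal, blood-forming liver to early postnatal liver. All 9 probes of the adult hepatocyte list rose, with miR-148a up by 4.48 ± 0.16 (log2 change ± SE, here and below) and miR-122 by 3.70 ± 0.19. The members miR-802 and miR-101a were at the floor in all 3 e15.5 livers and reached log2 values of 7.79 ± 0.54 and 6.94 ± 0.52 (SD, n = 3) at 2 weeks. Probes of the let-7 family, whose mature forms accumulate as tissues differentiate, also rose in 9 of 9 (8 after centring), led by let-7c (5.09 ± 0.29) and let-7b (5.06 ± 0.14). Erythroid miR-486 fell by 3.88 on the log2 scale and miR-144 fell by 2.04, and the leukocyte miRNAs miR-142-3p and miR-223 fell by 2.19 and 1.23.

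All 5 miR-30 probes (miR-30a, 4.70 ± 0.15), all 3 miR-29 probes (miR-29c, 3.71 ± 0.11) and all 5 of the miR-23/27/24 clusters (miR-23b, 4.49 ± 0.09; miR-27b, 4.47 ± 0.44) rose; after centring all remained higher except miR-24, which was not called (1.02). Both endothelial probes rose (miR-126-3p, 2.85 ± 0.10). Of the 7 probes of the miR-17~92 and paralogous clusters, which are linked to proliferation, 5 fell and 1 rose (miR-106b, 0.48, a call lost without 5 of the 12 livers in turn, adjusted p up to 0.097), and after centring all 7 fell (miR-106b, -1.27). The Dlk1-Dio3 cluster, a large imprinted miRNA cluster active in fetal tissues, had 46 probes, of which 20 fell and 2 rose (30 and 1 after centring); miR-543 fell by 3.78, miR-376b fell by 3.53 and miR-495 fell by 3.44. The erythroid miR-451 rose by 0.68 as deposited but turned to -1.06 after centring (as deposited, adjusted p = 0.017, but 0.073 without e15.5 mouse 3 and 0.068 without 2-week mouse 2). Of the 8 leukocyte probes, 3 rose (miR-150, 4.08 ± 0.26; miR-146a, 2.45 ± 0.13; miR-342-3p, at the floor in all e15.5 livers), 2 fell and 3 were not called. After centring 3 rose and 4 fell. Of the 5 stellate and mesenchymal probes, 4 rose, among them miR-145 (3.34 ± 0.18) and miR-199a-5p (0.87 ± 0.15). After centring 2 rose and 2 fell, as miR-199a-5p turned to -0.88 and miR-199a-3p from 1.31 to -0.43. Of the 6 biliary and epithelial probes, 3 rose (miR-429, 3.59 ± 0.33; miR-200b, 2.93 ± 0.19; miR-200a). After centring 3 rose and 1 fell.

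In all, 178 of 355 probes differed between 2 weeks and e15.5 (100 higher and 78 lower), and 73 of these calls involved floor values in at least 1 sample (21 higher, 52 lower). The 100 brightest probes were on average 1.75 higher on the log2 scale at 2 weeks. Centred on them, 68 probes were higher and 162 lower. Of these, 51 and 64 were above the floor in all 6 livers. The other centred calls involved floor values, which centring had moved. Of the 46 Dlk1-Dio3 probes, of which 30 fell after centring, 24 were above the floor in all 6 livers. Beside the calls above, the lists tested as sets (camera, preset correlation 0.01) gave 7 of 16 calls at adjusted p below 0.05. With an estimated correlation only the adult hepatocyte list was called (adjusted p = 0.014); the let-7 list then had adjusted p = 0.16, the miR-30 list 0.16, the miR-29 and miR-23/27/24 lists 0.19, and the Dlk1-Dio3 and the stellate and mesenchymal lists 0.20. The call of the stellate and mesenchymal list (adjusted p = 0.042) was also lost after centring (0.47) and after quantile normalisation (0.81).

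At 3 weeks against e15.5 all 9 hepatocyte-list probes rose, with miR-148a at 4.73 ± 0.16 and miR-22 at 3.94 ± 0.13, and 9 of 9 let-7 probes rose (let-7c, 4.89 ± 0.29). The let-7 count was 7 rose and 1 fell after centring: let-7i, up by 0.97 as deposited, turned to -0.41, and let-7e, up by 1.58, was no longer called (0.19, adjusted p = 0.053). In the Dlk1-Dio3 cluster 31 of 46 probes were lower and 1 (miR-154) was higher (34 and 1 after centring). Of the 46 probes, 15 were above the floor in all 6 livers. Among these, miR-376b fell by 9.06 ± 0.64 on the log2 scale, miR-495 by 7.66 ± 0.43 and miR-410 by 6.30 ± 0.42. Their 3-week log2 values were low, at 2.56 ± 1.51, 3.45 ± 0.85 and 3.62 ± 0.70 (SD, n = 3). The size of these falls therefore depends on how background was subtracted. All 3 miR-29 probes rose (miR-29c, 4.49 ± 0.11), as did miR-21 (4.07 ± 0.28) and all 5 miR-30 probes (miR-30a, 4.16 ± 0.15).

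Among blood-cell miRNAs, miR-486 fell by 3.56 and miR-144 fell by 1.57, while miR-451 was 0.71 higher as deposited (adjusted p = 0.012, and 0.054 without e15.5 mouse 3) and -0.68 after centring. Of the 8 leukocyte probes 3 rose and 3 fell (3 and 5 after centring). Those that rose were miR-150 (3.44 ± 0.26), miR-146a (2.30) and miR-342-3p, at the floor in all e15.5 livers; miR-142-3p fell by 2.40, miR-223 fell by 2.13 and miR-146b was at the floor in 2 of 3 livers at 3 weeks and in none at e15.5 (adjusted p = 0.015, lost without e15.5 mouse 3 or 3-week mouse 1 or 2, 0.053 to 0.062). Of the miR-17~92 and paralogous clusters 5 of 7 fell (7 after centring), including the combined miR-106a+miR-17 probe (-1.31 ± 0.18). Between 3 weeks and e15.5, 207 probes differed (91 higher, 116 lower; 100 of these calls involved floor values), and after centring 64 were higher and 177 lower around a shift of 1.39. Of the centred calls, 48 higher and 55 lower were of probes above the floor in all 6 livers. The camera test gave 6 list calls. With an estimated correlation the hepatocyte list kept its call (adjusted p = 0.010), whereas the let-7, Dlk1-Dio3 and miR-30 lists each had adjusted p = 0.12, the miR-29 list 0.14 and the miR-23/27/24 list 0.15.

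The comparison of 7 weeks with e15.5 set the young adult against the fetal liver, with the smallest shift of the 3 (0.27). The largest rises among probes measured in all 6 livers were miR-29c (4.84 ± 0.11), miR-21 (4.36 ± 0.28), let-7c (4.12 ± 0.29) and miR-29a (4.02 ± 0.10); miR-29c and miR-29a are known repressors of extracellular matrix transcripts. The adult hepatocyte list rose again in 9 of 9, with miR-22 at 3.57 ± 0.13, miR-148a at 3.37 ± 0.16 and miR-192 at 3.03 ± 0.18. The erythroid probes all fell, miR-486 by 5.0 and miR-144 by 4.34, and miR-451, which had been higher at 2 and 3 weeks only as deposited, fell by 0.55 (adjusted p = 0.046), a call lost when any 1 liver but 7-week mouse 1 was left out (11 of 12; adjusted p = 0.060 to 0.16). Of the 8 leukocyte probes 3 rose, 2 fell and 3 were not called, with the same counts of rises and falls after centring: miR-150 (2.78 ± 0.26), miR-146a (1.94) and miR-342-3p, from the floor, rose, while miR-142-3p fell by 3.63 and miR-223 fell by 3.21. All 7 miR-17~92 and paralogous probes fell, miR-93 by 3.31 and the combined miR-20a+miR-20b probe by 2.97.

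Of the 9 let-7 probes 7 rose, let-7i fell by 0.41 and let-7e was not called (-0.20; after centring it fell, -0.47). Of 46 Dlk1-Dio3 probes 32 fell and 1 rose: miR-434-3p fell by 5.05, while miR-376b, miR-495 and miR-410 were at the floor in all 3 livers at 7 weeks after log2 values of 11.62 ± 0.11, 11.11 ± 0.20 and 9.92 ± 0.36 (SD, n = 3) at e15.5. The probes of the other lists moved apart: the biliary miR-429 was at the floor in all 7-week livers, miR-200a, above the floor in 1 of 3 e15.5 livers and in all 7-week livers, was called (adjusted p = 0.016, but 0.064 without e15.5 mouse 1 and 0.079 without e15.5 mouse 2), miR-200b was not called, and the stellate and mesenchymal list had 2 up and 2 down. Both endothelial probes rose. In all 159 probes differed (66 higher, 93 lower; 72 of these calls involved floor values), against 84 higher and 68 lower after quantile normalisation. Of the 7 list calls, the estimated correlation kept the hepatocyte list (adjusted p = 0.0069) and gave let-7 0.22, Dlk1-Dio3 0.10, miR-29 0.10, miR-30 0.10, miR-17~92 0.14 and miR-23/27/24 0.17.

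**Figure D2:**
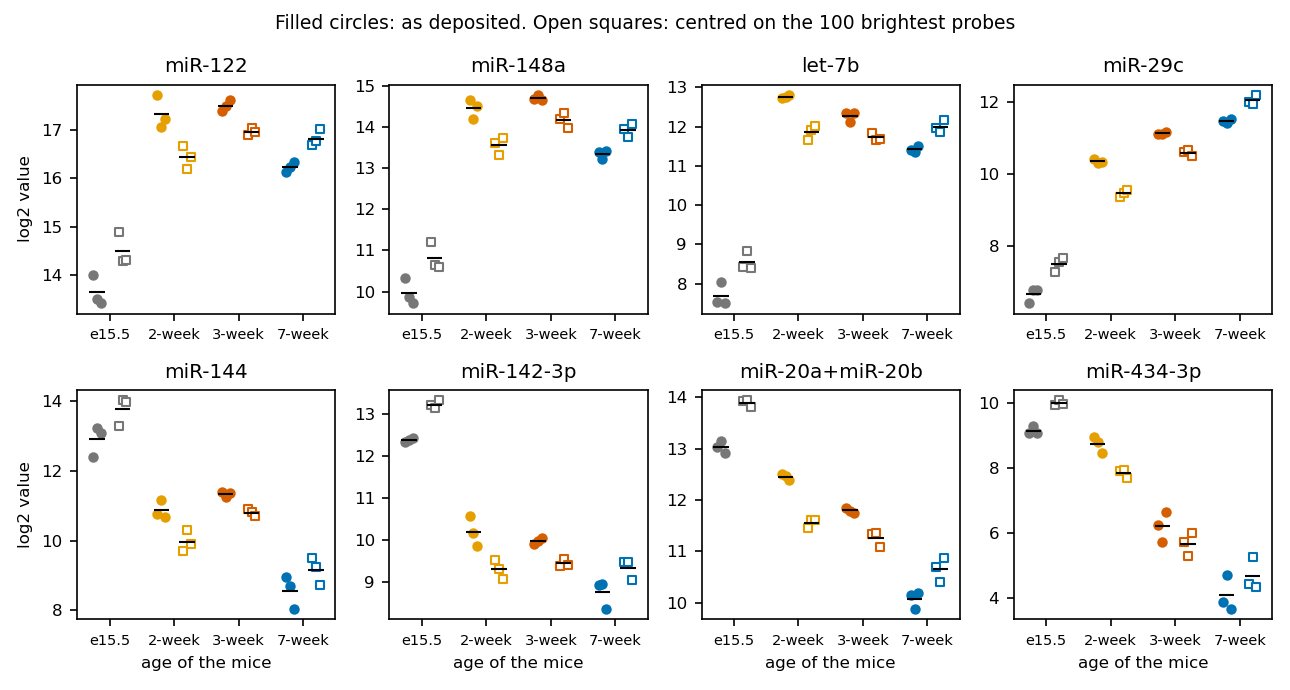
Log2 values of 8 miRNAs in all 12 livers by age, as deposited (filled circles) and centred on the 100 brightest probes (open squares), with lines at the means. The miR-29c values at 7 weeks lie above all earlier values on both scalings, and those of miR-434-3p below all earlier values as deposited.

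**Figure D3:**
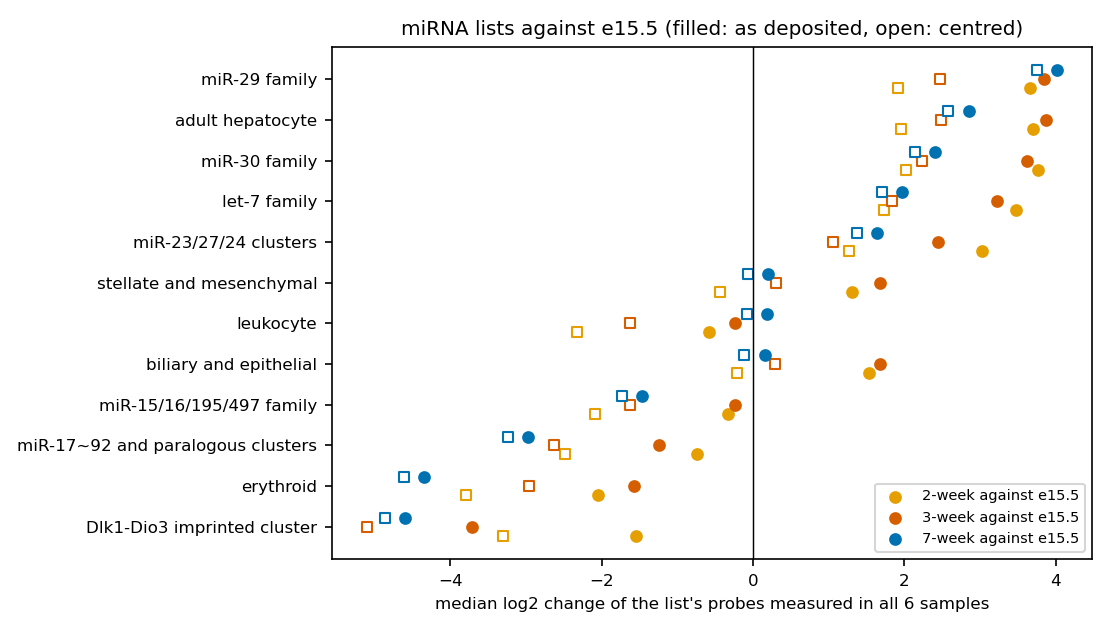
Median log2 change against e15.5 of the probes of each list that were above the floor in all 6 livers of the comparison, shown for lists with at least 3 such probes, as deposited (filled circles) and centred (open squares). The miR-29, hepatocyte, miR-30 and let-7 lists lie above 0 and the Dlk1-Dio3, erythroid and miR-17~92 lists below 0 in all 3 comparisons.

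From 2 to 3 weeks, the interval around weaning, 55 probes fell as deposited, 19 of them in the Dlk1-Dio3 cluster. Of its 46 probes none rose and 27 were not called, and its call as a list was lost with an estimated correlation (adjusted p = 0.14). In this cluster miR-376b fell by 5.53, miR-495 and miR-410 fell by 4.22 each, and miR-434-3p fell by 2.53, and after centring 19 fell and 1 rose. The falls of miR-376b, miR-495 and miR-410 ended at low 3-week log2 values (2.56, 3.45 and 3.62), so their size is uncertain. The number of Dlk1-Dio3 probes above the floor went from 25 to 30 per liver at 2 weeks to 15 or 16 at 3 weeks. Over all 355 probes this number also went down, from 192 to 209 per liver at 2 weeks to 159 to 168 at 3 weeks. Of 355 probes only miR-29c rose as deposited (0.78 ± 0.11, adjusted p = 0.00052), against 9 after centring. The stellate miR-199a-3p (-0.92 ± 0.15), the leukocyte miR-223 (-0.90 ± 0.12) and the biliary miR-429 (-1.79 ± 0.33) and miR-200b (-1.25 ± 0.19) fell, and each stayed lower after centring. After quantile normalisation none of these 4 was called (adjusted p = 0.11, 0.19, 0.60 and 0.057).

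None of the 9 hepatocyte-list probes was called, although after centring 4 rose, among them miR-22 (0.49) and miR-148a (0.61). In all 56 probes differed (1 higher, 55 lower; 17 with floor values), against 9 higher and 36 lower after centring on a shift of -0.36 and 6 higher and 20 lower after quantile normalisation. Of the centred calls, 9 higher and 19 lower were of probes above the floor in all 6 livers. All 4 list calls were lost with an estimated correlation, where the Dlk1-Dio3, hepatocyte and miR-29 lists each had adjusted p = 0.14 and let-7 0.50.

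**Figure D4:**
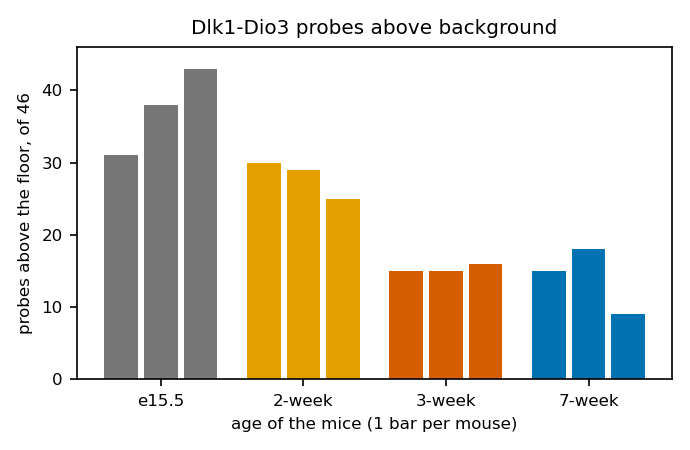
Number of the 46 Dlk1-Dio3 probes above the background floor, 1 bar per liver, grouped by age. The bars run from 31 to 43 at e15.5, 25 to 30 at 2 weeks, 15 or 16 at 3 weeks and 9 to 18 at 7 weeks. Over all 355 probes the numbers above the floor were 212 to 311, 192 to 209, 159 to 168 and 173 to 248 at these ages.

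Between 3 and 7 weeks the calls in many lists depended on the scaling, because the 100 brightest probes were on average 1.12 lower at 7 weeks. The changes below kept their call after centring. The hepatocyte miRNA miR-802 fell by 3.67 as deposited and its centred change was -2.55. As deposited miR-122 and miR-148a also fell (by 1.27 and 1.36), but they were not called after centring (-0.15 and -0.24). The difference from miR-802 was not tested. The Mest-hosted miR-335-5p fell by 2.82, the erythroid miR-144 fell by 2.77, miR-301a fell by 2.45 and the miR-106b cluster members miR-93 and miR-106b fell by 2.13 and 2.07. All 7 miR-17~92 and paralogous probes fell, 4 of them also after centring. Among probes measured in all 6 livers 3 rose and 83 fell as deposited, against 23 and 17 after centring. The 3 were miR-29b (0.59 ± 0.21), miR-34c (0.49 ± 0.15), a p53-responsive miRNA, and miR-29c (0.35 ± 0.11). As deposited these calls were lost without 10, 4 and 5 of the 12 livers in turn, 3-week mouse 1 among them each time (adjusted p = 0.15, 0.083 and 0.076 without it). The centred changes were 1.71, 1.61 and 1.46 (adjusted p = 0.00014, 0.00023 and 4.5e-06).

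As deposited, 6 of 9 hepatocyte probes fell and none rose, whereas after centring 2 rose (miR-22, which changed from -0.37 to 0.75, and miR-192, from -0.68 to 0.44; the deposited fall of miR-22 was lost without 9 of the 12 livers in turn, with adjusted p up to 0.17, and that of miR-192 without 3-week mouse 3, 0.052, or 7-week mouse 1, 0.054) and 1 fell (miR-802). The let-7 list fell in 8 of 9 and in 2 of 9 after centring, and the leukocyte list went from 1 rise and 3 falls to 4 rises. In all 147 probes differed, 42 higher and 105 lower; of the 42, 33 were at the floor in all 3-week livers, with 7-week means between 1.31 and 28.5 linear units. Centring gave 63 higher and 36 lower, and quantile normalisation 33 and 36. None of the 5 list calls held with an estimated correlation (adjusted p = 0.41 for the hepatocyte and miR-17~92 lists, 0.42 for let-7 and miR-30, 0.44 for miR-23/27/24).

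Across the whole postnatal span, 7 against 2 weeks, all 3 miR-29 probes rose (miR-29c, 1.12 ± 0.11; miR-29b, 1.07 ± 0.21; miR-29a, 0.36 ± 0.10), on the deposited and the centred scale. Lower at 7 weeks were miR-434-3p (-4.64 ± 0.31), miR-335-5p (-3.45 ± 0.22), miR-301a (-3.11 ± 0.23), miR-125a-5p (-2.80 ± 0.20) and let-7i (-2.02 ± 0.09), each also after centring. Of the Dlk1-Dio3 probes 24 fell and none rose, and after centring 16 fell and 2 rose. In all 154 probes differed (26 higher, 128 lower; 58 with floor values), against 49 higher and 58 lower after centring on a shift of -1.48, and 35 and 58 after quantile normalisation. Of the centred calls, 27 higher and 30 lower were of probes above the floor in all 6 livers. All 7 list calls were lost with an estimated correlation (adjusted p = 0.36 for each).

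Tested over the 4 ages at once, 193 of 355 probes differed, and over the 3 postnatal ages 148 did; of the 114 probes measured in every liver these were 102 and 91. The brightest probes at e15.5 were miR-720 (18.4 ± 3.4% of the signal, since reclassified as a tRNA fragment), miR-122, the miR-20a+miR-20b probe (5.2 ± 0.3%) and miR-144 (5.0 ± 1.6%). At 7 weeks miR-122 and miR-720 were followed by miR-22 (6.6 ± 0.3%), miR-148a (4.2 ± 0.3%) and miR-126-3p (4.1 ± 0.2%). The remaining lists held few measured probes. The 3 muscle, 3 pluripotent cell and 1 pancreas probes were at the floor in all 2- and 3-week livers, and 2 muscle and 2 pluripotent cell probes fell against e15.5 at each postnatal age, a call lost after quantile normalisation. Of 3 neural probes miR-137 was above the floor only in the 2-week livers. In the miR-15/16 family miR-15a and miR-15b fell against e15.5 at all 3 ages and miR-195 rose from the floor. Of the 6 probes of that family, 1, 2 and 1 rose and 2, 2 and 3 fell at 2, 3 and 7 weeks. After centring 1 rose and 4 fell at each age. In the miR-34 family miR-34c fell at 3 weeks (-0.44 ± 0.15, adjusted p = 0.030, lost without 4 livers in turn and 0.087 without 3-week mouse 1). In the miR-181 family miR-181a rose at 2 weeks (1.96 ± 0.13, not called after centring, 0.21) and at 3 weeks (0.97 ± 0.13), where it turned to -0.41 after centring. Adjusted over the list alone, counts of called members were the same as over all probes for every list against e15.5, except that 5 and not 4 miR-23/27/24 probes rose at 7 weeks. Between postnatal ages they were higher for let-7 (5 and not 4 fell), Dlk1-Dio3 (22 and not 19) and the endothelial list (2 and not 1) at 3 against 2 weeks. They were also higher for let-7 (9 and not 8) and the miR-15/16 family (1 rise and not 0) at 7 against 3 weeks, and for the hepatocyte (6 and not 5) and miR-30 (5 and not 4) lists at 7 against 2 weeks.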

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

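Alternatives added after the data were seen were the 2 log2(linear) scales, centring on the median of the 114 always measured probes, and testing only those probes. Centring on the median of all probes was not run because 4 of 12 sample medians lie at the floor. The miR-122 change at 7 weeks against e15.5 kept its direction and call under every alternative, with 2.49 to 2.78 when 1 liver was left out. Quantile normalisation called 26 probes at 3 against 2 weeks, 69 at 7 against 3 weeks, 93 at 7 against 2 weeks and 90 over the postnatal ages; list calls for these 3 pairs were 2 each, the Dlk1-Dio3 and miR-29 lists, neither of which was called as deposited at 7 against 3 weeks, so that all 5 deposited calls there were lost. Equal counts also hid exchanges: at 2 weeks against e15.5 centring on the 100 brightest probes lost the stellate and mesenchymal list and added miR-17~92, and at 3 against 2 weeks it lost let-7 and added the erythroid list. Centring on the 100 brightest probes gave 2 and 3 list calls for 7 against 3 and 7 against 2 weeks; of the 2, the miR-17~92 list was also called as deposited and the miR-29 list was not, so that 4 of the 5 deposited calls were lost. Centring on the median gave as many, and called 97 probes at 7 against 3 weeks. The upper 50% of probes gave 0 and 1 list calls for these pairs. With an estimated correlation 1 list was called at each age against e15.5 and 0 in each postnatal pair. Testing only the 114 always measured probes, where fewer can be called by construction, gave 95, 97 and 87 calls at 2, 3 and 7 weeks against e15.5, 37, 87 and 96 for 3 against 2, 7 against 3 and 7 against 2 weeks, and 106 and 96 over the 4 and the 3 postnatal ages, with 4, 2, 1 and 1 list calls at 2 weeks against e15.5 and in the postnatal pairs. Apart from leaving out livers, the other counts stayed within 1.5 times. Leaving out 1 liver gave 145 to 217, 172 to 250 and 133 to 169 calls at 2, 3 and 7 weeks against e15.5. The postnatal pairs (3 against 2, 7 against 3, 7 against 2) gave 50 to 62, 113 to 170 and 128 to 181. Over the 4 and 3 ages the counts were 189 to 247 and 133 to 184. The highest counts at 7 against 3 weeks and over the 3 ages came without 7-week mouse 3 (182 probes at the floor, against 129 and 107 in the other 7-week livers). All other highest counts came without e15.5 mouse 1 (143 probes at the floor, against 64 and 44 in the other e15.5 livers). List calls ranged from 6 to 8, 6 to 7 and 7 to 8 against e15.5, 2 to 5 in the 3 against 2 week and the 7 against 3 week pairs (2 without 2-week mouse 3 and without 3-week mouse 1), and 3 to 7 in the 7 against 2 week pair (3 without 7-week mouse 3). Of all probes, 9 and 8 were called in opposite directions as deposited and after centring on the 100 brightest at 2 and 3 weeks against e15.5, 5 at 7 against 3 weeks and 8 at 7 against 2 weeks. Among the changes named in the text, directions turned as follows, first after quantile normalisation, then after centring on the 100 brightest probes, then on the median: miR-451 at 2 weeks against e15.5 (-0.23, -1.06, -1.09) and at 3 weeks (-0.083, -0.68, -0.64), miR-199a-5p (-0.64, -0.88, -0.90), miR-199a-3p (-0.40, -0.43, -0.46) and miR-106b (-0.65, -1.27, -1.29) at 2 weeks, let-7i at 3 weeks (-0.099, -0.41, -0.37), and, at 7 against 3 weeks, miR-22 (0.63, 0.75, 0.69) and miR-192 (0.17, 0.44, 0.39). After the 2 centrings alone, miR-181a turned at 3 weeks against e15.5 (-0.41, -0.37) and miR-122 at 7 against 2 weeks (0.38, 0.39). The uncalled miR-22 change at 3 against 2 weeks was -0.077 after quantile normalisation and ran from -0.0030 without 2-week mouse 3 to 0.28 without 2-week mouse 1. These scalings remove the shift of bright probes by construction; the cause of the shift was not tested further here. No pairing by mouse number was seen, although 3 livers per age could hide one. Over the 114 always measured probes, deviations of same-numbered mice correlated between -0.41 and 0.52 (median 0.033). Those of mice with other numbers correlated between -0.55 and 0.45 (median 0.013). Of 12 samples, 3 correlated best with their own number. With the number as a block, calls went to 171, 207, 151, 50, 129 and 138 in the 6 pairs and to 193 and 142 over 4 and 3 ages, and list calls to 7, 6, 7, 3, 5 and 7. The signal over background limits dim probes: 241 of 355 were at the floor in at least 1 liver.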

Other observations

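The tests on the total signal, on miR-154 and on neighbouring genes were chosen after the results were seen. Biliary miR-429 and miR-200b were at 9.22 ± 0.08 and 9.39 ± 0.13 at 2 weeks, but at 7 weeks miR-429 lay at the floor in all 3 livers while miR-200b was at 6.62 ± 0.12. The oncogene-associated miR-21 rose from 8.24 ± 0.41 at e15.5 to 12.60 ± 0.35 at 7 weeks, and miR-193 and miR-195 were at the floor in all e15.5 livers and above it in all postnatal ones.

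The total signal was higher at 2 and 3 weeks than at e15.5 and 7 weeks, by 3.31-fold at 2 weeks against e15.5. Totals divided by the step of each sample still differed by 3.25-fold. This cannot decide on a scaling factor per sample, because the step was estimated only from gaps between 0.5 and 1.5. A step outside that range could not appear. Signal taken by miR-122 alone does not account for the difference in totals, since totals without miR-122 differed by 2.46-fold. A difference in RNA input or assay run between ages may be the source and cannot be told apart from age: totals within an age differed by at most 1.27-fold, which both would give, and no control probes were used here. Age itself stays open and untested. A search for an unlabelled run by floor values was replaced after its values were seen: 4 probes were measured in all e15.5 and 7-week livers and at the floor in all others, and 4 in all e15.5 and 2-week livers alone.

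In the Dlk1-Dio3 cluster, of which 20, 31 and 32 of 46 probes fell at 2, 3 and 7 weeks against e15.5, miR-154 rose from 8.22 ± 0.07 (SD, n = 3) at e15.5 to 10.89 ± 0.22, 11.07 ± 0.07 and 9.79 ± 0.07 at 2, 3 and 7 weeks. It was not alone at 2 weeks, where 24 probes were not called and miR-496, above the floor in 2 of 3 livers, was called higher (adjusted p = 0.036, 0.066 after centring and up to 0.11 with 1 liver left out), but was the 1 member called higher at 3 and at 7 weeks. The overall shift in signal is not the source, since its centred change at 7 weeks against e15.5 was still 1.298 (adjusted p = 7.2e-06). Of the other 7 members measured in all 6 livers of that comparison, the highest change was -1.85. A candidate explanation is that the miR-154 probe also captures another RNA, which cannot be told apart from separate regulation of miR-154 without probe sequences.

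A hypothesis that neighbouring miRNA genes change together was tested outside the Dlk1-Dio3 cluster on 89 always measured probes with 1 matched gene. The match was by name, and whether a miRNA is also made from a further gene was not checked. Some of the pairs tested share probes. All pairings of miR-106b, miR-25 and miR-93, and all of miR-23b, miR-24 and miR-27b, are among them. For 15 pairs within 10000 bases, the median difference between centred log2 changes at 7 weeks against e15.5 was 0.823, against 2.02 for shuffled changes (permutation test with 100000 draws, one-sided p = 0.0080). This is consistent with joint regulation of neighbours, although similar sequences within a cluster could give it too, and miR-144 and miR-451 (-4.61 and -0.82) differed by 3.79.

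For each pair of ages the real grouping was 1 of 10 splits of the 6 livers, too few for a share under 0.05. The real counts of 178, 207 and 159 calls at 2, 3 and 7 weeks against e15.5 stood beside highest counts of 1, 1 and 18 in the other splits, and those of 56, 147 and 154 at 3 against 2, 7 against 3 and 7 against 2 weeks beside 2, 1 and 2. Over the 4 ages, 1 of 100 splits (the real one) gave as many as 193 calls, with 83 the highest of the others. Over the 3 postnatal ages 1 of 100 gave as many as 148, with 122 the highest. A share of 1 in 100 is the smallest these splits can give, so an accidental grouping is unlikely for both but not excluded. The splits do not separate age from RNA input or assay run.

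A test of whether the 33 rises from the 3-week floor to 7 weeks lay near background was also run and then not weighed, after its value was seen. Its limit of 32 linear units lay above the highest 7-week mean of the 33 probes (28.5). The 0 of 124 below was therefore largely fixed by the choice of limit. Among probes above the floor in all 3 livers at 7 weeks, as 20 of the 33 were, 20 of 40 with a mean there under 32 linear units (50%) were at the floor in all 3-week livers, against 0 of 124 brighter ones; of the 33, 28 were above the floor in all e15.5 livers and 17 at it in all 2-week livers.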
